A study of Schizosaccharomyces pombe with 12 samples.

How the data were processed

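RNA was measured in 12 libraries of Schizosaccharomyces pombe, 3 of each of 4 groups: WT and the A, Q and R mutants of histone H2B. Per the labels, total RNA was extracted with Trizol, mRNA was enriched with oligo(dT), and the cDNA was amplified by PCR and sequenced. The submitters' processing notes name fastp, Bowtie2, HISAT2, StringTie, RSEM and DESeq2, without roles or versions. The genome build, the annotation and the handling of strand are not given in the sources used here. Groups were taken from the sample titles and genotype labels.

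Per the file headers, the deposited tables hold a count and an FPKM value per gene and library. The counts are whole numbers. FPKM is a measure scaled for gene length and for the total count of the library. The implied gene length deviated between libraries by at most 14.199% for genes with at least 100 counts in every library. The deposited log2 ratios are, from their values, the log2 of the ratio of the group means of FPKM and not fitted fold changes. Each deposited p-value and FDR comes from the authors' own test, whose role among the tools is not given. The authors' deposited tables of changed genes hold the genes with an FDR below 0.05 and a log2 ratio of at least 1 in size, except 1 gene of R that meets this rule and is not listed.

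Each full table holds 5160 genes, of which 32 had 0 counts in all libraries and 24 are loci assembled by StringTie. Of the gene identifiers 5109 matched the reference gene table (assembly ASM294v3) and 51 did not. The reference was used only for names, for the order of genes along the chromosomes, and, with BLAST 2.17.0, for copies of a gene elsewhere, taken as at least 95% identity over at least 50% of its length. Total counts per library were 20050394, 16131962 and 15461002 in WT replicates 1, 2 and 3, 16504014, 16865857 and 17100237 in A, 15329416, 16608465 and 16556527 in Q, and 17493119, 16936164 and 16777441 in R. The floor of 3 counts was between 0.15 and 0.196 CPM. The 10 most abundant genes took between 7.5% and 10.5% of the counts, and between 5064 and 5087 genes had a count. Reads carry no molecular identifiers, so counting intervals (95%, exact) and floors cover counting error only.

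Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which kept 5024 and left out 136, and libraries were scaled with TMM. All 12 libraries entered 1 quasi-likelihood fit with group as the only term, and 6 contrasts were tested. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The common biological coefficient of variation was 0.186 and the prior degrees of freedom 4.16. SEs were obtained from the log2 fold change and the F statistic and are approximate. All adjusted p-values for genes are two-sided and from edgeR unless another tool is named.

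37 gene lists with 526 names were fixed, of which 510 names matched a gene, and 35 lists had at least 3 tested members. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over lists within a comparison. None of the list calls held with a correlation estimated for each list. The genes named were chosen by a rule. For each mutant it took htb1 and the 8 largest rises and 8 largest falls with an adjusted p below 0.05, a change of at least 2-fold, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. It also took the 3 members with the lowest p of each list described, up to 4 genes per direction between mutants, where fewer than 4 pass without the fold limit, and up to 6 per direction for genes shared by all 3 mutants. Of the genes taken for the lists only examples are named, and 1 other gene that the rule took is not reported here. Genes outside this rule were chosen after their values were seen: hta1 beside htb1, the genes at the right end of chromosome I that the rule did not take, and the examples of gene ontology terms. The groups, tests, gene lists, the rule and the alternatives were fixed before the data were examined, except those said to have been chosen later.

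Whether replicate numbers pair the libraries was checked by the correlation of deviations from the group means. For Q and R these were 0.32, 0.4 and 0.29, and for R and A 0.18, 0.32 and 0.19, all above 0.1, so the numbers were taken to pair these groups. For A and WT (0.12, 0.28 and 0.05), Q and WT (-0.08, 0.08 and -0.03), R and WT (-0.06, 0.18 and -0.07) and Q and A (-0.18, 0.2 and 0.13) they were not. Nothing in the labels says that equal numbers share a batch. The values reported between Q and R and between R and A come from the planned fit without a block, with the block as an alternative. Of the 12 libraries 8 were closest to a library of the same number in another group. Counts of replicates of a group differed by more than sampling noise in every pair, with chi-square per degree of freedom between 15.8 and 204.3, so no library was counted as a copy of another.

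Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a fit of only the groups compared, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), an adjusted p below 0.01, fry, and leaving out each library in turn. For shared calls, unchanged groups and the controls they share were simulated 20 times. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

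The fit was tested on simulated data of 5024 genes with known fold changes. In the simulation of A against WT, 29.9% of genes changed 1.5-fold, 76.1% of genes changed 2-fold and 95.5% of genes changed 4-fold were recovered, with 6 false among 148 calls. For Q against WT the shares were 31.3%, 85.1% and 95.5%, with 4 false among 153, and for R against WT 25.4%, 86.6% and 95.5%, with 5 false among 146. In all 3 simulations camera called a list that had been shifted and did not call a list that had not. The simulated genes varied independently and only a single list of each kind was drawn, so this does not give the rate of false list calls in the real data. All simulated groups had the same spread, while the real WT libraries lay closer together than most mutant libraries, so the false gene calls hold for that setting only.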

Results

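Gene expression was profiled by RNA sequencing in 12 libraries of the fission yeast Schizosaccharomyces pombe. 3 libraries came from the wild type (WT) and 3 from each of 3 histone H2B mutants. In the mutants the lysines at positions 5, 10 and 15 of H2B were replaced together, with alanine (A), with glutamine (Q) or with arginine (R). Arginine keeps the positive charge of an unacetylated lysine, glutamine is often used in place of an acetylated lysine, and alanine has neither property. The series title ties acetylation of these lysines to the repair of DNA double-strand breaks, and its design sets each mutant against the wild type. The label of A replicate 2 gives position 16 in place of 15 for the third substitution. Gene counts summed to between 15329416 (Q replicate 1) and 20050394 (WT replicate 1) per library. 3 counts, taken here as the floor, corresponded to between 0.15 and 0.196 CPM, the count scaled to the total of its library. Means are CPM ± SD of 3 libraries, and log2 fold changes carry an approximate standard error (SE). Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples. Other differences between the strains, at the htb1 locus or elsewhere, cannot be told apart from effects of the substitutions.

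The 3 WT libraries lay close together, while the mutant libraries spread more widely. The first principal component, with 44.5% of the variance, placed the WT libraries between -28.8 and -22.9, the A libraries between -10.1 and 4.8, the Q libraries between 8.1 and 30.1 and the R libraries between 4.5 and 34.8. The second, with 19.7%, set the R libraries (14.4 to 22.2) apart from the A and Q libraries (-18 to -6.1). In each mutant, replicate 2 had the highest first component. It also had the highest level of several strongly changed genes: SPAC977.18 reached 332 CPM in A replicate 2, 1090 CPM in Q replicate 2 and 878 CPM in R replicate 2, against 111, 644 and 260 CPM in the next highest library of the same mutant.

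**Figure D1:**
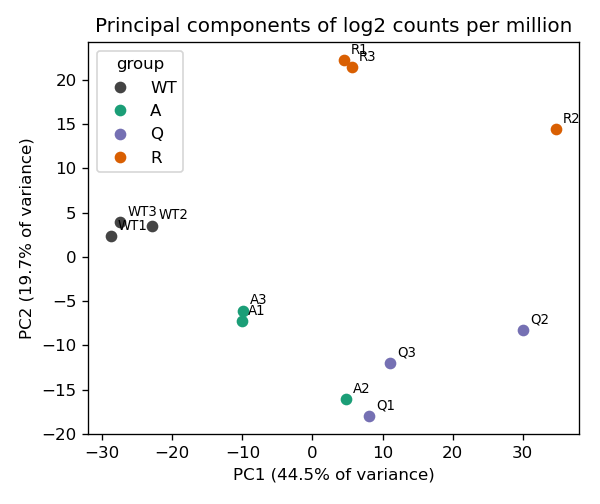
First and second principal components of log2 CPM, with 44.5% and 19.7% of the variance, 1 point per library. The WT libraries sit between -28.8 and -22.9 on the first component, and the R libraries lie at 14.4 or above on the second.

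The mutated gene itself was called higher than WT in A and R and lower in Q. htb1 (SPCC622.09, chromosome III), the gene for histone H2B, stood at 3210 ± 182 CPM in WT (n = 3). It rose to 10800 ± 5360 CPM in A (log2 fold change 1.75, SE 0.27, adjusted p = 0.0174, edgeR quasi-likelihood test). It fell to 1200 ± 74 CPM in Q (log2 fold change -1.42, SE 0.27, adjusted p = 0.00528). In R it was 5690 ± 240 CPM (log2 fold change 0.82, SE 0.27, adjusted p = 0.0438). The A libraries ranged from 5930 to 16500 CPM. The substitutions do not delete htb1, so no loss of its transcript is expected by which to check the labels. The call in R was lost without any 1 of WT replicate 1 (adjusted p = 0.132), WT replicate 2 (0.0988), WT replicate 3 (0.107), R replicate 1 (0.0703), R replicate 2 (0.0934) and R replicate 3 (0.0856), and with limma on the deposited FPKM values (0.0742). The call in A was lost without WT replicate 1 (0.0967), WT replicate 2 (0.0627) or WT replicate 3 (0.101).

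Both annotated neighbours of htb1 were examined as well; hta1 was chosen after its values were seen. sec5 (SPCC622.10c), a predicted subunit of the exocyst, which tethers secretory vesicles at the plasma membrane, fell in all 3 mutants. Its level was 432 ± 42.5 CPM in WT, 137 ± 27.4 in A (log2 fold change -1.66), 132 ± 28.1 in Q (-1.71) and 146 ± 35.1 in R (-1.56), with adjusted p of 0.00714, 0.00197 and 0.000782. hta1 (SPCC622.08c), which encodes histone H2A and lies on the other side of htb1, fell in Q from 421 ± 9.47 to 232 ± 16.2 CPM (log2 fold change -0.86, adjusted p = 0.00528). It was 318 ± 74.3 CPM in A (adjusted p = 0.159) and 425 ± 62.7 CPM in R (adjusted p = 0.958).

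**Figure D2:**
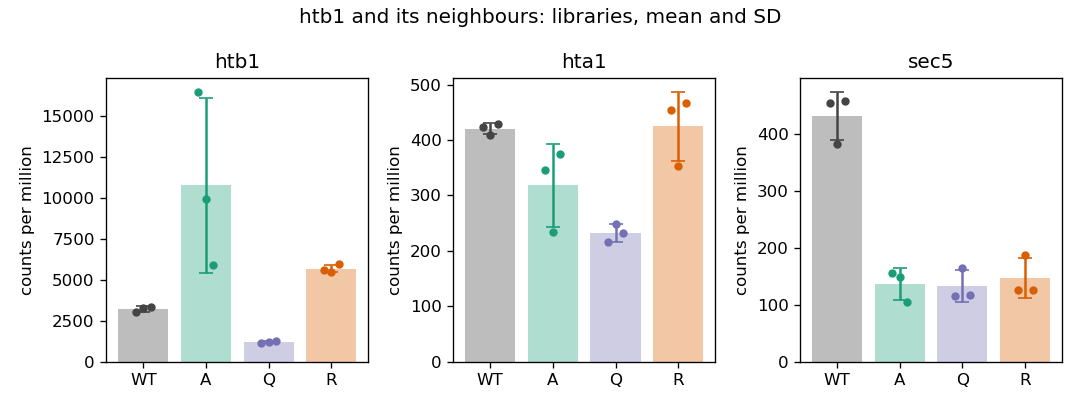
Level in CPM of htb1, hta1 and sec5 in each group; points are the 3 libraries, bars their mean and error bars the SD. htb1 is highest in A (10800) and lowest in Q (1200), and sec5 lies between 132 and 146 in the mutants against 432 in WT.

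The alanine mutant addresses which transcripts change when the lysines are replaced by a small neutral residue. Among its largest rises, ste4 (SPAC1565.04c), an adaptor in the pheromone signalling pathway, rose from 9.09 ± 1.03 to 32.6 ± 3.41 CPM (log2 fold change 1.84, SE 0.18, adjusted p = 0.000927). mei2 (SPAC27D7.03c), an RNA-binding protein required for meiosis, rose from 3.07 ± 0.856 to 15.8 ± 6.99 CPM (2.37, SE 0.45, 0.0197). The transporter gene mfs3 (SPBC36.03c) rose from 147 ± 46.6 to 537 ± 45.8 CPM (1.86, SE 0.25, 0.00714). The remaining 5 of the 8 largest rises were SPAC977.18 (log2 fold change 3.1), SPBPB2B2.18 (3.02), fub2 (2.73), SPAC186.07c (2.57) and SPAC977.04 (1.85). fub2 is annotated as a proteasome regulator, and SPAC186.07c as a predicted hydroxyacid dehydrogenase.

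Among the falls in A, no count was recorded for uga1 (SPAC19D5.07), a GABA transaminase, or for dut1 (SPAC644.05c), a predicted dUTPase, in any A library. Their WT levels of 6.43 ± 1.06 and 5.69 ± 1.07 CPM put them at least 35.8-fold and at least 31.7-fold lower, with the floor taken per library. Each overlaps another annotated gene, and the counting is not described, so reads from that position may have been assigned differently between libraries. trz2 (SPBC3D6.03c), a mitochondrial tRNA-processing endonuclease, fell from 273 ± 31.6 to 78.3 ± 28.3 CPM (log2 fold change -1.8, SE 0.45, adjusted p = 0.0476). The ribonuclease gene tri1 (-1.54), the RecA family gene rlp1 (-1.4), SPAC27F1.10 (-1.82) and SPAC959.06c (-1.4) also fell.

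In total 209 of 5024 tested genes were called in A (edgeR, Benjamini-Hochberg adjusted p), 137 higher and 72 lower, and 68 of them changed at least 2-fold. This count rested on every library: it was 4 without WT replicate 1, 2 without WT replicate 2, 7 without WT replicate 3, 97 without A replicate 1, 14 without A replicate 2 and 67 without A replicate 3. Of the 17 genes singled out, 4, 2, 5, 10, 6 and 10 were still called in these fits, and ste4 and sec5 were called in all of them. DESeq2 called 546 genes, a fit of the A and WT libraries alone 933. Of the genes called by limma on FPKM values 50.5% were higher, against 65.6% of the 209. In a fit without replicate 2 of A, Q and R, chosen after the data were seen, 650 genes were called in A, 2039 in Q and 1242 in R.

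Of the 35 gene lists tested, 4 were called in A by camera with a preset correlation of 0.01. Of 118 tested subtelomeric genes, 16 rose and 2 fell (28 and 4 adjusted over the list alone; median log2 fold change 0.51; camera adjusted p = 0.000271, and adjusted p = 0.112 with an estimated correlation). They included SPBC1348.02, which rose from 202 ± 3.82 to 389 ± 39.1 CPM (log2 fold change 0.94), and the cell-surface gene pfl9, which rose from 10.1 ± 1.45 to 22.6 ± 2.99 CPM (1.17). SPBC1348.02 belongs to a family of similar membrane proteins, so its counts could hold reads of relatives. Of 4 galactose genes, gal1 (20.3 ± 0.778 to 43.4 ± 1.77 CPM) and gal7 (18.6 ± 2.98 to 36.1 ± 1.83 CPM) rose and 2 were not called (4 rose adjusted over the list alone; camera adjusted p = 0.0017, and adjusted p = 0.112 with an estimated correlation). By their identifiers the galactose genes also belong to the subtelomeric list, so the calls of the 2 lists are not separate. Among 35 proteasome genes 4 rose, for instance rpn2 (273 ± 12.2 to 565 ± 100 CPM), and 9 rose adjusted over the list alone (median 0.21; camera adjusted p = 0.000271, adjusted p = 0.984 with an estimated correlation). The proteasome call was lost without A replicate 2 (adjusted p = 0.0818).

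The fourth list, of 19 genes of nitrogen starvation and amino acid transport, had 1 lower member, the ornithine carbamoyltransferase gene arg3 (78 ± 2.46 to 56.2 ± 5.42 CPM), and 3 adjusted over the list alone (median -0.24; camera adjusted p = 0.0206, adjusted p = 0.666 with an estimated correlation). Its call was lost without WT replicate 3 (0.0897) or A replicate 2 (0.062). Other splits of the same 6 libraries called up to 11 lists. Without any 1 of the 3 WT libraries no more than 7 genes were called in all, and most examples lost their calls there: SPBC1348.02 without WT replicates 1 or 2 (0.0594 and 0.0519), pfl9, gal1 and gal7 without any WT library or A replicate 2 (0.0553 to 0.102), and rpn2 and arg3 without any 1 of the 6 libraries (0.0592 to 0.171). Of 24 genes of mating and early sexual differentiation 7 rose and none fell (8 and 2 adjusted over the list alone), and camera did not call the list (adjusted p = 0.241).

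The glutamine mutant, which addresses the effect of an acetyl-lysine substitute, showed the largest number of changed genes. fub2 (SPBP4G3.03) rose from 17.8 ± 2.91 to 575 ± 323 CPM (log2 fold change 5.01, SE 0.75, adjusted p = 0.00297) and SPAC977.18 from 21.4 ± 4.38 to 662 ± 416 CPM (4.95, SE 0.71, 0.00269). mei2 rose to 43.1 ± 17.1 CPM from 3.07 ± 0.856 (3.82, SE 0.47, 0.00197). SPAC186.07c rose from 5.36 ± 1.88 to 122 ± 79.2 CPM (4.49, SE 0.68, 0.00297). Further rises were those of SPAC977.02 (4.69), SPBPB2B2.18 (3.98) and the amino acid permease gene isp5 (3.58). isp5 was uneven among the Q libraries, at 55.2, 654 and 221 CPM. SPAC977.02 belongs to a family with near-identical subtelomeric copies, so its counts are uncertain.

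uga1 and dut1 had no count in any Q library, at least 35.8-fold and at least 31.7-fold below WT. SPAC11D3.06, a predicted MatE family transporter, fell from 47.5 ± 7.95 to 3.93 ± 3.25 CPM (log2 fold change -3.59, SE 1.05, adjusted p = 0.0218). Among the other largest falls, trz2 fell from 273 ± 31.6 to 47.3 ± 17.1 CPM (-2.53), the splicing factor gene prp38 from 116 ± 18.8 to 23.1 ± 4.51 CPM (-2.32), and the endoribonuclease gene swt1 from 6.29 ± 1.6 to 1.09 ± 0.524 CPM (-2.52). pdi4 (-2.32), a predicted protein disulfide isomerase, and gut2 (-2.3), a predicted glycerol-3-phosphate dehydrogenase, fell as well.

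In Q 1731 genes were called, 936 higher and 795 lower, and 409 changed at least 2-fold. The count was 968, 1083 and 841 without WT replicates 1, 2 and 3 and 1067 without Q replicate 2. SPAC11D3.06 lost its call without WT replicate 1 (adjusted p = 0.0552), WT replicate 3 (0.0581), Q replicate 1 (0.0528) or Q replicate 2 (0.0704), and gut2 without WT replicate 1 (0.0518) or Q replicate 2 (0.0591).

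Of 18 heat-shock chaperone genes 9 fell and 1 rose in Q (12 and 1 adjusted over the list alone), with a median log2 fold change of -0.49 (camera adjusted p = 0.000882, and adjusted p = 0.728 with an estimated correlation). hsp90 (SPAC926.04c) fell from 3210 ± 215 to 1500 ± 196 CPM (-1.1, adjusted p = 0.00372) and the Hsp70 gene ssa2 (SPCC1739.13) from 6890 ± 879 to 2180 ± 769 CPM (-1.66, 0.00472). Of 20 oxidative stress genes 6 fell and 1 rose, the same numbers adjusted over the list alone (median -0.42; camera adjusted p = 0.032, adjusted p = 0.728 with an estimated correlation). The transporter gene caf5 fell from 151 ± 24 to 35.9 ± 11.7 CPM and the thioredoxin gene trx1 from 462 ± 64.7 to 253 ± 33.5 CPM. This call was lost without Q replicate 2 (0.0866) or Q replicate 3 (0.0798).

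Of 35 proteasome genes 15 rose in Q and none fell (17 adjusted over the list alone; median 0.32; camera adjusted p = 8.81e-05, adjusted p = 0.728 with an estimated correlation); rpn2 reached 741 ± 163 CPM from 273 ± 12.2. Of the subtelomeric genes 45 rose and 12 fell (47 and 14 adjusted over the list alone; median 0.51; camera adjusted p = 0.00606, adjusted p = 0.364 with an estimated correlation), with pfl9 at 29.3 ± 2.82 CPM and SPBC1348.02 at 450 ± 59.1 CPM. Of the 4 galactose genes 3 rose, among them gal10 from 36.6 ± 5.99 to 111 ± 50.2 CPM (4 adjusted over the list alone; camera adjusted p = 0.0267, adjusted p = 0.412 with an estimated correlation). These 3 lists and the chaperones were called in each fit that left out 1 library. The galactose genes are also members of the subtelomeric list, so the calls of these lists are not separate.

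Of 72 ribosome biogenesis factors 21 fell and 8 rose in Q, the same numbers adjusted over the list alone (median -0.2; camera adjusted p = 0.0132, adjusted p = 0.776 with an estimated correlation); rrp12, an rRNA processing factor, fell from 404 ± 27.4 to 213 ± 10.4 CPM. Of 141 cytosolic ribosomal protein genes 18 rose and none fell (1 adjusted over the list alone; median 0.11; camera adjusted p = 0.0343, adjusted p = 0.841 with an estimated correlation), among them rpl902 (249 ± 8.49 to 397 ± 37.9 CPM). The latter list was made by name pattern and holds 3 RNase P subunit genes as well. Of 33 oxidative phosphorylation genes 7 rose and none fell, 7 also adjusted over the list alone (median 0.22; camera adjusted p = 0.0343, adjusted p = 0.841 with an estimated correlation). Of 7 thiamine genes 3 fell (4 adjusted over the list alone), among them pho4 from 54.8 ± 2.2 to 23.6 ± 4.23 CPM (camera adjusted p = 0.0386, adjusted p = 0.728 with an estimated correlation). Without Q replicate 2 none of these 4 lists was called (0.0866 for biogenesis factors and thiamine genes, 0.535 for ribosomal proteins, 0.359 for oxidative phosphorylation). The ribosomal proteins were also not called without WT replicate 1 (0.146), WT replicate 3 (0.157) or Q replicate 1 (0.111), nor oxidative phosphorylation without WT replicate 1 (0.0852) or WT replicate 3 (0.0638). Among all 5024 tested genes 936 were called higher and 795 lower in Q. The share called higher was thus smaller among the ribosomal protein genes than among all genes. Among the oxidative phosphorylation genes it was similar, while no member of either list was called lower. In all, 9 of 35 lists were called in Q, and other splits of the same libraries called up to 8.

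The arginine mutant addresses the effect of a residue that cannot be acetylated. It showed rises of mating genes, which Q and, for fewer genes, A showed as well, and a near loss of transcripts at 1 chromosome end. ste11 (SPBC32C12.02), the transcription factor that drives sexual differentiation, rose from 28.4 ± 4.94 to 238 ± 38.9 CPM (log2 fold change 3.07, SE 0.35, adjusted p = 0.000355). spk1 (SPAC31G5.09c), the MAP kinase of the pheromone pathway, rose from 10.4 ± 0.459 to 80.1 ± 38.6 CPM (2.95, SE 0.45, 0.00222), and mei2 from 3.07 ± 0.856 to 32.1 ± 17.4 CPM (3.39, SE 0.46, 0.000994). mfs3 rose from 147 ± 46.6 to 1070 ± 183 CPM (2.86, SE 0.26, 7.53e-05). fub2 (4.67), SPAC977.18 (4.44), SPAC977.02 (3.69) and the MADS-box transcription factor gene mbx1 (2.94) made up the rest of the 8 largest rises.

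In R 1218 genes were called, 662 higher and 556 lower, and 303 changed at least 2-fold. The count was 325, 630 and 347 without WT replicates 1, 2 and 3 and 502 without R replicate 2. With limma on FPKM values 1261 genes were called, of which 34.1% were higher, against 54.4% of the 1218. On that scale the median of all genes lay at -0.1, against -0.005 with the scaling used here, so levels in R are relative to the scaling chosen.

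5 of the 8 largest falls in R lay close together at the right end of chromosome I. In chromosome order toward the end these were SPAC186.04c (16.4 ± 0.222 CPM in WT, 0.246 ± 0.165 in R), SPAC186.05c (22.7 ± 2.13 and 0.123 ± 0.00395), the pyruvate decarboxylase gene pdc102 (32.4 ± 8.42 and 0.163 ± 0.0318), the aldo/keto reductase gene SPAC750.01 (131 ± 12.3 and 4.88 ± 2.47) and SPAC750.05c (36.8 ± 3.54 and 0.265 ± 0.23). Their log2 fold changes were -6.02, -7.45, -7.57, -4.74 and -7.07, with adjusted p of 1.29e-06, 4.3e-09, 1.47e-07, 1.5e-06 and 1.71e-05. SPAC186.04c, SPAC186.05c, pdc102 and SPAC750.05c had 12, 6, 8 and 13 counts in all over the R libraries, so the size of their fitted changes, here and against Q and A, is uncertain. From SPAC186.03 to the last tested gene there were 12 tested genes, of which 10 were called lower in R. The exceptions were SPAC186.07c (1.55 CPM in R, 5.36 in WT, adjusted p = 0.0915) and SPAC750.07c (0.103 and 0.531 CPM, 0.0769). This stretch was delimited after its values were seen. The next 2 genes on the centromere side, SPAC186.02c and pfl9, stood at 2.41 ± 0.154 and 14 ± 2.97 CPM in R, against 0.335 ± 0.128 and 10 ± 1.43 CPM in WT. 6 of the 12 genes, SPAC750.05c among them, have a near-identical copy elsewhere in the reference, so their counts are uncertain.

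**Figure D3:**
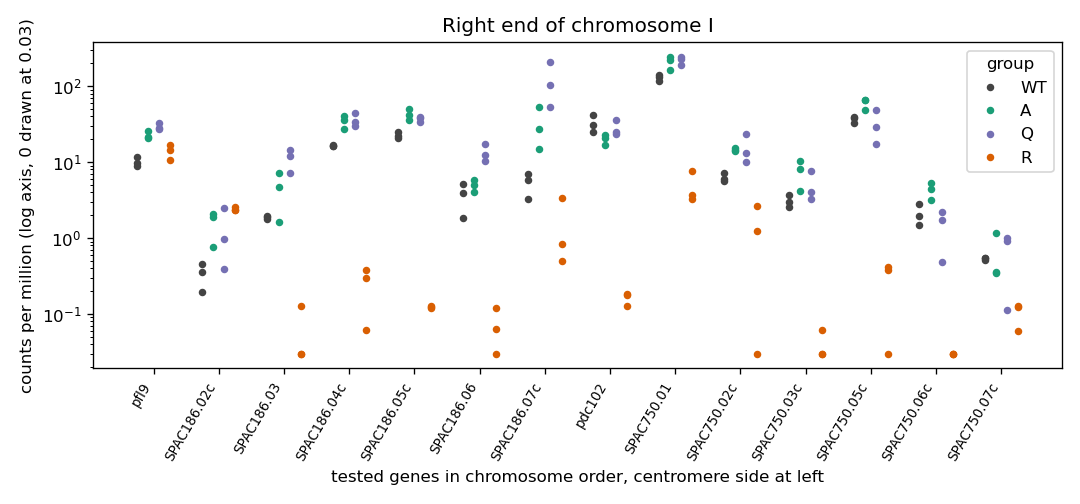
Level in CPM of the tested genes at the right end of chromosome I, in chromosome order; each point is 1 library, on a log axis with 0 drawn at 0.03. From SPAC186.03 onward the R libraries lie below the WT libraries, except for SPAC186.07c, where R replicate 2 (3.32) is above WT replicate 3 (3.27), with means of 0.123 against 22.7 for SPAC186.05c, while pfl9 is at 14 against 10.

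The other falls in R were uga1, with no count in any R library and at least 34.9-fold below WT, dut1 (0.125 ± 0.108 CPM) and cum1 (SPAC22G7.11c). cum1 had a single count over the R libraries against 12.8 ± 1.29 CPM in WT, a ratio of 628 with a 95% counting interval of 112 to 24900. It overlaps another gene, was uneven in the other mutants (5, 150 and 991 counts in A, 300, 0 and 0 in Q), and lost its call (adjusted p = 0.0436) without any 1 of the 6 libraries: 0.0914, 0.0756 and 0.0852 without WT replicates 1, 2 and 3, and 0.102, 0.137 and 0.096 without R replicates 1, 2 and 3.

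Of 24 genes of mating and early sexual differentiation 13 rose and 3 fell in R, the same numbers adjusted over the list alone (median 0.82; camera adjusted p = 0.00133, adjusted p = 0.665 with an estimated correlation). Of 8 M mating-type genes 6 rose and 1 fell, likewise over the list alone (median 1.39; camera adjusted p = 0.00452, adjusted p = 0.282 with an estimated correlation). The M-factor gene mfm2 rose from 41.2 ± 10.2 to 257 ± 53 CPM and the M-factor exporter gene mam1 from 37.9 ± 0.428 to 130 ± 23.2 CPM, while sxa2, a carboxypeptidase gene, fell from 30.5 ± 0.475 to 15.1 ± 0.767 CPM. Of 4 P mating-type genes 2 rose and 2 fell, likewise over the list alone (median -0.26; camera adjusted p = 0.812, adjusted p = 0.844 with an estimated correlation). map1, a MADS-box transcription factor gene, rose from 19 ± 3.81 to 59.4 ± 7.68 CPM and the protease gene sxa1 from 1030 ± 14.8 to 1680 ± 37.9 CPM, while the P-factor gene map2 fell from 99.6 ± 22.4 to 31.9 ± 18 CPM. The call of map2 was lost without WT replicates 1, 2 or 3 or R replicate 2 (adjusted p of 0.101, 0.0505, 0.0814 and 0.0813) and that of sxa1 without WT replicates 1 or 3 (0.0514 and 0.0511). Most M genes and the P genes are also in the list of mating genes, so these lists overlap. In Q 12 of the 24 mating genes rose and 5 fell, likewise over the list alone (median 0.57). Of the 8 M genes 4 rose and 1 fell in Q, 5 and 1 adjusted over the list alone (median 0.63). Camera called neither list in Q (adjusted p = 0.0744 and 0.108, and 0.728 for both with an estimated correlation). Fry, which does not compare a list with other genes, called both lists in Q (adjusted p = 0.0218 and 0.0146) and in R (0.00645 and 0.00109). Between Q and R 1 mating gene was higher and 1 lower in Q.

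Of 10 core histone genes 5 rose in R and none fell (6 adjusted over the list alone; median 0.45; camera adjusted p = 0.00973, adjusted p = 0.665 with an estimated correlation). hhf2, for histone H4, rose from 376 ± 45.1 to 597 ± 62.5 CPM. The other H4 genes hhf1 (0.85) and hhf3 (0.49) rose too, but their calls were lost without WT replicate 1 (adjusted p = 0.0611 and 0.0738) or WT replicate 3 (0.0512 and 0.0566), and htb1, also among the 5, lost its call without any 1 library. Of 18 heterochromatin and RNA interference genes 4 fell and none rose (8 and 1 adjusted over the list alone; median -0.51; camera adjusted p = 0.0196, adjusted p = 0.665 with an estimated correlation), among them tas3, a subunit of the RITS silencing complex, from 20.2 ± 1.37 to 9.24 ± 1.05 CPM.

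Of 141 ribosomal protein genes 27 rose and none fell in R (25 adjusted over the list alone; median 0.25; camera adjusted p = 7.89e-09, adjusted p = 0.665 with an estimated correlation), for instance rpl3402 from 19.5 ± 2.45 to 44.3 ± 3.43 CPM; on the FPKM scale the median of this list was 0.16. 10 of 35 proteasome genes rose and 1 fell (16 and 2 adjusted over the list alone; median 0.24; camera adjusted p = 0.00133, adjusted p = 0.665 with an estimated correlation), with pre6 rising from 168 ± 5.88 to 267 ± 21.3 CPM. Of 33 oxidative phosphorylation genes 6 rose and 1 fell (6 and 0 adjusted over the list alone; median 0.26; camera adjusted p = 0.00133, adjusted p = 0.665 with an estimated correlation). qcr9, an example, rose from 89.6 ± 6.13 to 152 ± 24.6 CPM, a call lost without WT replicate 1 (0.0521) or WT replicate 3 (0.0566).

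Of 18 heat-shock chaperone genes 5 fell in R and none rose (7 lower adjusted over the list alone; median -0.44; camera adjusted p = 0.0178, adjusted p = 0.665 with an estimated correlation), with the Hsp20 family gene SPCC338.06c falling from 126 ± 5.69 to 78.1 ± 3.49 CPM. Of 72 ribosome biogenesis factors 13 fell and 3 rose (11 and 3 adjusted over the list alone; median -0.16; camera adjusted p = 0.0478, adjusted p = 0.681 with an estimated correlation), for instance utp23 from 54.9 ± 1.34 to 35.2 ± 4.97 CPM; this call was lost without WT replicate 1 (0.13) or R replicate 2 (0.128). Of the subtelomeric genes 34 fell and 14 rose (38 and 17 adjusted over the list alone; median -0.34; camera adjusted p = 0.00452, adjusted p = 0.282 with an estimated correlation). Without the 12 genes at the right end of chromosome I, 24 fell and 14 rose and the list was not called (adjusted p = 0.172). Other splits of the same 6 libraries called up to 10 lists, as many as the 10 called in R.

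**Figure D4:**
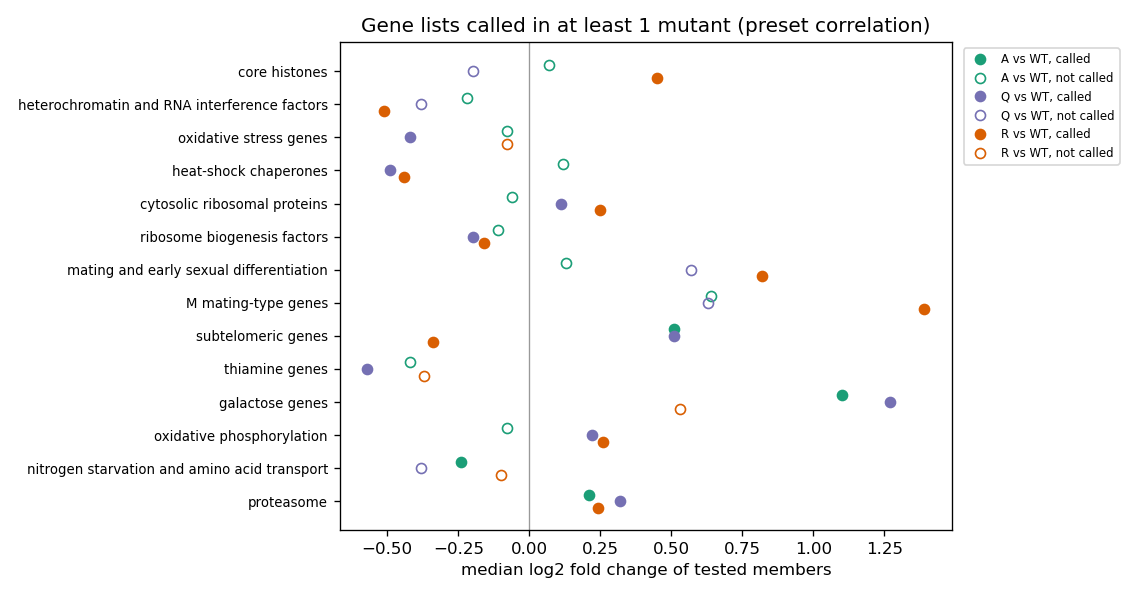
Median log2 fold change of the tested members of each gene list called in at least 1 mutant by camera with a preset correlation; filled points are called and open points not called. The subtelomeric median is 0.51 in A and Q and -0.34 in R, and the chaperone median is -0.49 in Q and -0.44 in R.

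Genes of DNA repair were examined because of the series title. No repair list was called in any mutant. Of 29 tested genes of homologous recombination repair 1 rose and 3 fell in A (3 and 3 adjusted over the list alone; camera adjusted p = 0.973), 7 rose and 6 fell in Q (7 and 6; 0.725) and 6 rose and 5 fell in R (6 and 5; 0.827). In A the median was 0.02 while camera's direction was down, and on the FPKM scale the median was -0.02. rdh54 (SPAC22F3.03c), a recombination helicase gene, rose from 9.84 ± 1.16 to 34.6 ± 3.83 CPM in Q (log2 fold change 1.82, adjusted p = 0.00426) and to 29.6 ± 17.1 CPM in R (1.59, 0.00745). rdl1 (SPAC17H9.03c), a RAD51D-like gene, fell from 26.6 ± 1.68 to 14.3 ± 2.47 CPM in A (-0.89, 0.0224) and 13 ± 1.09 CPM in Q (-1.03, 0.00413). The mediator gene swi5 rose in R from 3.58 ± 1.44 to 10.8 ± 3.24 CPM (1.58, 0.00685). The call of rdl1 in A was lost without WT replicate 1 (0.107), WT replicate 2 (0.0627), WT replicate 3 (0.109), A replicate 1 (0.0584) or A replicate 2 (0.0871).

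Of 5 end joining genes none was called in A, lig4 rose in Q (33.4 ± 3.62 to 54.8 ± 11.8 CPM) and 2 fell in R (adjusted over the list alone 0, 1 higher and 1 lower, and 2 lower; camera adjusted p = 0.973, 0.725 and 0.251). These 2 were xlf1 (4.32 ± 0.244 to 2.06 ± 0.457 CPM) and pku70 (45.4 ± 3.67 to 29.1 ± 0.231 CPM). The pku70 call (adjusted p = 0.031) was lost without any 1 of WT replicates 1, 2 and 3 (0.0661, 0.0802 and 0.0981) or R replicates 1, 2 and 3 (0.0607, 0.0792 and 0.0591), and xlf1 without WT replicate 1 (0.0521). Among 17 checkpoint genes, cds1, the replication checkpoint kinase, rose from 25 ± 2.44 to 74.4 ± 14.4 CPM in Q and rad3, the ATR kinase, from 50.8 ± 7.64 to 140 ± 54 CPM, and rad4 fell from 108 ± 3.31 to 72.8 ± 1.09 CPM. The checkpoint list had 3 rises and 2 falls in Q, the same numbers adjusted over the list alone (camera adjusted p = 0.566).

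Of 17 histone acetyltransferase and deacetylase genes 1 rose and none fell in A, 4 rose and 5 fell in Q and 2 rose and 1 fell in R (4 and 0, 5 and 6, and 1 and 1 adjusted over the list alone; camera adjusted p = 0.217, 0.719 and 0.603). mst2 rose from 77.3 ± 5.13 to 136 ± 15.1 CPM in A (0.82, adjusted p = 0.0252), 206 ± 51.9 CPM in Q (1.42, 0.00197) and 211 ± 15 CPM in R (1.45, 0.00047). ada2 fell in Q from 48.2 ± 2.41 to 29.8 ± 0.976 CPM and gcn5 in R from 31.4 ± 1.83 to 18.3 ± 3.36 CPM. The call of mst2 in A was lost without WT replicates 1, 2 or 3 or A replicates 2 or 3 (0.118, 0.0699, 0.116, 0.0685 and 0.0755), and that of gcn5 without WT replicates 1, 2 or 3 or R replicate 2 (0.086, 0.0556, 0.0686 and 0.0907).

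Many genes were called in more than 1 mutant. 152 genes were called in the same direction in all 3 mutants, 100 higher and 52 lower. This count was 4, 2 and 6 without WT replicates 1, 2 and 3, and 73, 8 and 49 without A replicates 1, 2 and 3. It was 368 with DESeq2, 434 in fits of only the groups compared, 362 with the replicate block and 5 at an adjusted p below 0.01. The highest of the 152 by their smallest fold were SPAC977.18, fub2, mei2, mfs3, ste4 and SPAC977.04. The lowest were uga1, SPBC4F6.11c, SPAC6C3.05, dut1, SPAC27F1.10 and sec5. SPBC4F6.11c, a predicted asparagine synthase, and SPAC6C3.05 had no count in any mutant library, against 3.74 ± 1.87 and 1.48 ± 0.76 CPM in WT, and DESeq2 called neither in A (adjusted p = 0.19 and 0.287), Q (0.103 and 0.177) or R (0.121 and 0.2). SPAC27F1.10 lost its call in R without WT replicates 1, 2 or 3 or R replicate 2 (0.0772, 0.0537, 0.0783 and 0.0528), and SPAC6C3.05 without WT replicate 3 (0.0514). In A both lost their calls without any 1 of the 6 libraries (0.0684 to 0.15), and SPBC4F6.11c without WT replicates 1, 2 or 3 or A replicate 2 (0.104, 0.0662, 0.0603 and 0.0677).

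Among the highest of the 152, SPAC977.04 lost its call in R without WT replicates 1, 2 or 3 or R replicate 2 (0.0555, 0.0501, 0.0586 and 0.0556) and in A without any 1 of the 6 libraries (0.0615 to 0.15). In A the calls of SPAC977.18 and mei2 were lost without any 1 WT library or A replicate 2 (0.0758 to 0.13), that of fub2 without any 1 WT library, A replicate 2 or A replicate 3 (0.0857 to 0.188) and with limma on FPKM values (0.0631), and those of mfs3, uga1 and dut1 without WT replicate 2 (0.0519 for each), uga1 also without WT replicate 1 (0.0594).

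A and Q shared 128 higher and 63 lower genes, A and R 107 and 55, and Q and R 480 and 319. Independent lists of these sizes would share 25.5 and 11.4, 18.1 and 8, and 123.3 and 88. Unchanged groups, simulated with controls that were also simulated and common to all of them, shared 0. They had at most 0.07 calls per group on average, so they say little about these counts. Fold changes correlated across 4970 genes with r = 0.78 for A and Q, 0.55 for A and R and 0.68 for Q and R, against 0.5, 0.5 and 0.51 in the simulations; genes are not independent replicates. The covariances were 0.248, 0.177 and 0.327 against 0.031, 0.031 and 0.032. The simulated values already hold a sharing of controls, with the same spread in all groups. With 3 control libraries the real controls cannot be split, so how much their sharing adds could not be checked directly. The simulations also hold no effect shared by libraries of the same number, to which part of the excess for Q and R and for R and A may be due. The count for A and Q was 4, 2 and 7 without WT replicates 1, 2 and 3 and 94, 9 and 63 without A replicates 1, 2 and 3; for A and R it was 4, 2, 6, 76, 12 and 52. For Q and R it fell from 799 to 211, 386 and 204 without WT replicates 1, 2 and 3 and to 372 without R replicate 2.

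Between the glutamine mutant, with a neutral residue at the 3 positions, and the arginine mutant, with a positive one, 183 genes differed, 104 higher and 79 lower in Q. The largest differences lay at the right end of chromosome I, where Q had SPAC186.05c at 37.2 ± 2.6 CPM (log2 difference 8.16, SE 0.25, adjusted p = 1.38e-09) and pdc102 at 28.2 ± 7.03 CPM (7.37). SPAC186.03, a predicted L-asparaginase gene, and SPAC186.06 had 2 and 3 counts in all over the R libraries, so Q was higher by a ratio of 272 (95% counting interval 74.8 to 2250) and 217 (74 to 1060). SPAC186.03 has a near-identical copy elsewhere, so its counts are uncertain. htb1 was lower in Q than in R (-2.24, SE 0.28, 0.00107), as was hta1 (-0.87, 0.0162). The glucanase gene agn1 was 297 ± 122 CPM in Q and 1200 ± 202 CPM in R (-2.01, 0.00176), and the hexose transporter gene ght2 188 ± 18.8 and 663 ± 291 CPM (-1.82, 0.0274). gon7 had no count in Q and 9.28 ± 3.64 CPM in R, at least 51.7-fold apart (adjusted p = 0.0388), but overlaps another gene. Of the subtelomeric genes 39 were higher in Q and none lower, and of the core histone genes 4 were lower. The 39 include genes at the right end of chromosome I.

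The calls of gon7 and ght2 were lost without Q replicate 1 (adjusted p = 0.092 and 0.0837), Q replicate 2 (0.0657 and 0.0596), Q replicate 3 (0.107 and 0.108), R replicate 1 (0.0974 and 0.101) or R replicate 3 (0.118 for both), that of gon7 also with DESeq2 (0.0832) and that of ght2 in a fit of the Q and R libraries alone (0.0513). That of hta1 was lost without Q replicates 1 or 3 (0.0604 and 0.0525) or R replicates 1 or 3 (0.0646 and 0.0725). The count of 183 was 88 and 91 without Q replicates 1 and 3, 61 and 51 without R replicates 1 and 3, and 462 without R replicate 2. It was 344 with DESeq2 and 42 in a fit of the Q and R libraries alone. With the replicate number as a block 207 genes were called, of which 169 were among the 183 and 51.7% were higher in Q. With limma on FPKM values 77% of the calls were higher in Q, against 56.8%, and the median of all genes shifted to 0.13 from 0.02.

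The glutamine and alanine mutants differed in 2 genes, both lower in Q (edgeR). htb1 was 1200 ± 74 CPM in Q and 10800 ± 5360 CPM in A (log2 difference -3.17, SE 0.29, adjusted p = 0.000612), and SPAC11D3.09, a predicted agmatinase gene, 16.4 ± 0.511 and 38 ± 8.17 CPM (-1.21, SE 0.16, 0.0108). At an unadjusted p below 0.05 there were 926 genes. DESeq2 called 115, the fit with the replicate block 96 (50% of them higher in Q) and limma on FPKM values 1. Without replicate 2 of A, Q and R 453 genes were called. The count was 183 without A replicate 2, 184 without Q replicate 1, and 1 without Q replicate 2 or Q replicate 3, where SPAC11D3.09 had an adjusted p of 0.0627 and 0.0711. In a fit of the Q and A libraries alone none was called, and htb1 had an adjusted p of 0.0555. A replicate 2 and Q replicate 1 deviated from the mean of all libraries alike (correlation 0.66 across genes).

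Between the arginine and alanine mutants 124 genes differed, 44 higher and 80 lower in R. The largest differences again lay at the right end of chromosome I: SPAC186.05c was 0.123 ± 0.00395 CPM in R and 42.8 ± 6.86 in A (log2 difference -8.36, SE 0.25, adjusted p = 1.02e-09), SPAC750.05c 0.265 ± 0.23 and 59.8 ± 9.18 CPM (-7.77) and SPAC186.04c 0.246 ± 0.165 and 34.7 ± 6.87 CPM (-7.1). SPAC750.03c had 1 count over the R libraries, a ratio of 367 (95% counting interval 65.4 to 14500), and like SPAC750.05c has a near-identical copy elsewhere. mam2, the P-factor receptor gene, was higher in R (102 ± 27.7 against 28.5 ± 3.77 CPM; 1.83, 0.0146), as were agn1 (1200 ± 202 against 391 ± 91.1 CPM; 1.62, 0.00661), ima1 (1.75, 0.0488) and omh5 (1.61, 0.0398). htb1 was not called (-0.93, adjusted p = 0.0828). Of the subtelomeric genes 34 were lower in R and none higher, of the heat-shock chaperones 3 were lower, and of the ribosomal protein genes 6 were higher. The 34 include genes at the right end of chromosome I.

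With the replicate number as a block, which the check of the deviations favoured for this pair, 364 genes differed between R and A, of which 54.1% were higher in R against 35.5% without it. The count was 57 and 67 without A replicates 1 and 3 and 82 and 51 without R replicates 2 and 3. The call of mam2 was lost without A replicate 1 (adjusted p = 0.0788) or A replicate 3 (0.0549), that of ima1 without any 1 of A replicates 1, 2 and 3 (0.149, 0.0815 and 0.133) or R replicates 1, 2 and 3 (0.0549, 0.117 and 0.0871), and that of omh5 without A replicates 1, 2 or 3 (0.144, 0.0673 and 0.118) or R replicates 2 or 3 (0.105 and 0.0831).

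The authors' deposited tables of changed genes list 148 genes for A (77 higher and 71 lower), 428 for Q (253 and 175) and 343 for R (144 and 199). An FDR below 0.05 is given in the authors' deposited full tables for 1266 genes in A, 2080 in Q and 1950 in R.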

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

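The tests of the low counts in R of genes without a copy of at least 90% identity, of a loss of the chromosome end and of silencing at all ends were chosen only after the result was seen; the first test of shared reads was set beforehand, but its sequence search was made more sensitive after its first output was seen. The differences between mutants are of genes whose changes against WT ran in opposite directions in 2 mutants, with a direct test between the mutants (edgeR, adjusted p). Groups of 3 libraries are too small for a test of single libraries.

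htb1, the mutated gene, was higher than WT in A and R and lower in Q, with log2 differences of -3.17 between Q and A (adjusted p = 0.000612) and -2.24 between Q and R (0.00107). The subtelomeric gene SPBC1348.02, of a family of similar membrane proteins, rose in A and Q and fell in R, with differences of -1.96 between R and A (3.06e-06) and 2.17 between Q and R (1.01e-06). Its neighbour SPBC1348.04 did likewise, with -2.75 between R and A (1.15e-05) and 3.01 between Q and R (4.85e-06).

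At the right end of chromosome I, SPAC186.04c rose in A and Q and fell in R, with differences of -7.1 between R and A (adjusted p = 2.86e-07) and 7.15 between Q and R (1.76e-07). SPAC186.05c had differences of -8.36 between R and A (1.02e-09) and 8.16 between Q and R (1.38e-09). Between Q and R, SPAC750.01 differed by 5.48 (3.79e-07). The fitted differences of SPAC186.03 (7.86, 0.000177) and SPAC186.06 (7.6, 1.69e-05) rest on 2 and 3 counts over the R libraries and are no bounds.

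From SPAC186.03 to this end 10 of 12 tested genes were called lower in R, and reads shared with near-identical copies elsewhere could account for part of this, since only 2 of the 6 consecutive genes called at least 2-fold lower lack such a copy, under the 3 set beforehand as evidence against it. For the genes with no copy of even 90% identity the tables argue against shared reads. Among them SPAC186.04c, SPAC186.05c and pdc102 fell from 16.4, 22.7 and 32.4 CPM in WT to 0.246, 0.123 and 0.163 CPM in R. In all 4 of these 5 were called at least 2-fold lower, but this number adds little, as the stretch was chosen by its low counts in R. The tables also argue against silencing of similar strength shared by the ends of chromosomes I and II in R. The 60 outermost genes of the other 3 ends had a median log2 fold change of -0.05 (95% bootstrap interval -0.32 to 0.46). By end the medians were -0.35 at the left end of chromosome I and 0.25 and 0.03 at the ends of chromosome II. A milder fall, or a fall of single genes at these ends, is not excluded. A bound of 1 CPM against loss of the chromosome end in the R strain was passed by SPAC750.01, at 7.72 CPM in an R library, but this decides nothing, because a copy with 92.7% identity may supply its reads. SPAC186.07c, whose closest match has 70.3% identity, had 77 counts over the R libraries, reaching 3.32 CPM in R replicate 2. This goes against loss in all cells, but it is 1 gene, seen mostly in 1 library, so loss in all cells, loss in most cells and silencing of this end alone, brought about by the substitution or not, cannot be told apart without DNA data.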

How the results depend on the processing

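The fit without replicate 2 of A, Q and R, the subtelomeric test without the right end of chromosome I, the list medians on the FPKM scale and all counts of genes shared by the 3 mutants were chosen only after the result was seen; the other alternatives were planned. No called gene named here and no called list changed its direction under an alternative run for it. The share of calls that were higher lay on the other side of 50% in R with limma on FPKM values (34.1% and 34.8%, against 54.4%) and between R and A with the replicate block (54.1%, against 35.5%). Between Q and R, at 56.8%, it fell to 47.6% in a fit of only the groups compared, 48.7% without R replicate 2 and 47.6% without replicate 2 of A, Q and R; between Q and A it was 69.6% without Q replicate 1, against 0. On the FPKM scale 8 list medians changed sign, all of lists not called in that comparison. Of the values of named genes 4291 had the same call, 501 lost it and 146 gained it, and of the values of lists 1090, 52 and 14. RLE size factors and no filter on low counts moved no count of calls by over 1.5 times. The cause was not tested, except that a stricter threshold leaves fewer calls by construction.

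DESeq2 called 546 genes in A (112 at least 2-fold), 344 between Q and R, 115 between Q and A and 444 between R and A, with 479 shared by A and Q, 393 by A and R and 368 by all 3 mutants (152 as reported). A fit of only the groups compared called 933 in A (126 at least 2-fold), 42 between Q and R and 0 between Q and A, with 722 shared by A and Q, 498 by A and R and 434 by all 3; edgeR called 2 between Q and A in the fit of all libraries, and 926 had an unadjusted p below 0.05. With the replicate block there were 464 calls in A (103 at least 2-fold), 96 between Q and A and 364 between R and A, with 429 shared by A and Q, 376 by A and R and 362 by all 3; the counts of genes in Q, in R, between Q and R and shared by Q and R, and of lists, moved by under 1.5 times. Limma on FPKM values called 1 gene between Q and A with either pseudocount, and htb1 in R had a log2 fold change of 0.73 with either. An adjusted p below 0.01 left 6 genes in A (5 at least 2-fold), 602 in Q (254), 275 in R (146), 46 between Q and R, 1 between Q and A and 43 between R and A, with 6 shared by A and Q, 5 by A and R, 159 by Q and R and 5 by all 3. Without replicate 2 of A, Q and R 650 genes were called in A and 334 were shared by all 3. Between Q and R 882 genes were called in that fit, between Q and A 453 and between R and A 464. With an estimated correlation 0 lists were called in A, Q or R, and fry, which does not compare a list with other genes, called 2 in A, 7 in Q and 5 in R.

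Leaving out 1 library gave between 2 and 97 genes in A, 841 and 1681 in Q, 325 and 1108 in R, 51 and 462 between Q and R, 1 and 184 between Q and A, and 51 and 172 between R and A. At least 2-fold, there were 2 to 46 in A and 156 to 390 in R. Between 2 and 189 genes were shared by A and Q, 2 and 222 by A and R, 204 and 844 by Q and R, and 2 and 213 by all 3. The log2 fold change of htb1 ranged from 1.3 to 2.04 in A and 0.78 to 0.85 in R, and 4 to 10 lists were called in Q. Depth limits genes near the floor of 3 counts: with 0 counts in a group their folds are bounds, with 1 to 3 they carry counting intervals or are said to be no bounds, and with slightly more they are fitted values and uncertain.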

Other observations

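The tests of gene ontology terms, of other splits of the samples and of the likeness of A replicate 2 and Q replicate 1 were chosen only after the result was seen; those of overlapping genes and of counting noise were set beforehand.

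Of 64 tested genes annotated to endocytosis 22 rose and 3 fell in Q (camera adjusted p = 0.0467, and adjusted p = 0.921 with an estimated correlation) and 19 rose and 3 fell in R (0.0163 and 0.913). Camera called 3 terms in Q and 7 in R, and other splits of the same libraries called up to 26 and 7. arc4, a subunit of the actin-nucleating Arp2/3 complex, rose from 34.2 ± 4.93 CPM in WT to 83.9 ± 17.3 in A, 100 ± 19.3 in Q and 96.6 ± 20.9 in R. The clathrin adaptor gene yap18 rose from 68.6 ± 2.92 to 159 ± 24, 219 ± 32 and 182 ± 63.8 CPM, and pan1, of the endocytic actin patch, from 335 ± 11.5 to 569 ± 59.6, 572 ± 80.2 and 587 ± 53.2 CPM. Of 20 genes of protein targeting to the vacuole 9 rose in Q and none fell (0.0467, and 0.921 with an estimated correlation), for instance the sorting receptor gene vps10 from 120 ± 1.91 to 269 ± 60.8 CPM. In R, 23 of 73 genes of transport from the endoplasmic reticulum to the Golgi rose and 3 fell (0.0163), and 3 of 13 genes of ATP biosynthesis rose and none fell (0.0163), among them atp2 from 1950 ± 119 to 2930 ± 156 CPM. Of 49 genes of mitotic sister chromatid segregation 6 fell and 2 rose in R (0.0476), with the kinetochore gene spc24 falling from 121 ± 11.8 to 75.6 ± 16.8 CPM. In A camera called none of 346 terms, of which 44 had an unadjusted p below 0.05. These examples were not followed with single libraries left out. With an estimated correlation none of the terms was called; the lowest adjusted p was 0.99 in A, 0.921 in Q and 0.913 in R.

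Genes near the chromosome ends had medians above WT in A and Q at each of the 4 ends tested. Among the 20 outermost tested genes the median log2 fold changes in A were 0.87 and 1.07 at the left and right ends of chromosome I and 0.86 and 0.99 at those of chromosome II. In Q they were 0.74, 1.19, 1.19 and 1.09, and in R -0.35, -2.29, 0.25 and 0.03. In Q 7 consecutive genes from SPAC977.01 to SPAC977.06 at the left end of chromosome I were called at least 2-fold higher, against at most 5 in 1000 shuffled gene orders; many of these genes have close relatives at other ends, so their counts are uncertain. The longest run in R held 6 genes, against at most 5 after shuffling, and that in A 2, against 3.

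8 genes had at most 3 counts in each library of a group and at least 20 in each library of another, among them uga1, dut1 and SPBC4F6.11c, which were low in all 3 mutants. The test of counting noise decides nothing: the choice of these genes alone required a summed count of at least 60 in the higher group, so their median of 323 could not fall under the bound of 30. Reads moving between overlapping genes may account for some of them: 75% overlap another protein-coding gene, against 34.5% of genes of like level. The 95% range of random draws of such genes ended at 62.5%, and single draws may lie above it. The share of overlaps cannot say which genes of the 8 are affected, and a change of transcription in the mutants stays open as well.

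A replicate 2 deviated from the mean of all libraries more like Q replicate 1 (correlation 0.66 across genes, which are not independent replicates) than like A replicate 1 (0.08) or A replicate 3 (0.01). A Q culture labelled as A is argued against by htb1, which in A replicate 2 stood 7.75 times above the highest Q library. A shared day or batch of A replicate 2 and Q replicate 1 could give a correlation such as 0.66, but the labels name no day. The different substitution in the label of A replicate 2 stands on 1 library, so it cannot be told apart from other differences of that library.

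For each comparison the 6 libraries make 10 splits, too few for a share under 0.05. Only the real split, 1 of the 10, called as many genes in A (209, highest other 0), Q (1731, 0), R (1218, 0) and between R and A (124, 2), and likewise for genes changed at least 2-fold in A (68, 0), Q (409, 0) and R (303, 0). Between Q and R 2 splits called as many (183, highest other 239), and between Q and A 2 (2, 190). If replicate numbers pair Q with R and R with A, which the labels do not say, 4 of the splits part all 3 pairs. Of these only the real one called any gene (highest other 0 for each), and the split with 239 parts 1 pair. The lowest share that 4 splits can give is 1 of 4, so they decide nothing. The split of A replicates 1 and 3 with Q replicate 3 against the rest called 190 genes, far above the real count of 2, which points to a structure of these samples. For gene lists 10 splits called as many in A (4, highest other 11), 1 in Q (9, 8) and 2 in R (10, 10). For gene ontology terms the numbers were 10 in A (0, 29), 8 in Q (3, 26) and 4 in R (7, 7).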
